A study of Homo sapiens and Mus musculus with 9 samples.

How the data were processed

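Total RNA of the MDA-MB-231 breast cancer line was measured on 9 arrays, per the labels, which describe cells transfected with an inducible DACH1 construct and a receptor plasmid and selected with Zeocin and G418. The deposited values are the intensity of each probe set on a linear scale, 1 column per array, with no missing and no 0 values among the 22283 probe sets. The scanner software, background correction and summary method were not given in the sources used here. After the top and bottom 2% of values were left out, the mean signal was 500.1 to 500.2 on every array, so the authors' values had been brought to a common level before deposit, by a method not given in the sources used here. No detection calls were used here. The number of arrays limits the precision.

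The labels give no condition for any array, so all 9 were kept as 1 group and no test between groups was made. Nothing in the labels says that the arrays came from separate cultures. The organism label of array 1 is mouse and that of the other 8 human, array 2 names another receptor plasmid than the other 8, and the source name of array 4 includes DACH1. All were kept. Before the data were examined, a test of log ratios against 0 had been planned for the case that the table held ratios. It held single-channel values, so that test, with its array weights, robust variant, sign flips, set tests, threshold on fold and turning of directions, was not run. The plan for single-channel values was followed, which gives each array's values, the level and SD of each gene list and the correlation between arrays.

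Signals were multiplied by a factor per array (0.938 to 1.04) that set its median to the mean of the 9 medians, 153. Log values are log2 of the signal plus a pseudocount of 1.53, which is 1% of the median signal. Ratios between arrays are of scaled signals with no pseudocount. Differences of low signals are understated on the log scale. A probe set was called above background on an array when its signal exceeded the highest of the 27 Bacillus control probe sets there (40.5 to 84.9), a bound chosen after the data were seen. It was above background overall if this held on all 9 arrays. The limit of 2 times between the highest and the lowest array was also chosen then. Passing the background bound does not by itself show that a gene is expressed.

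Gene names came from the platform annotation, in which 19065 probe sets have 1 gene symbol, 1043 several and 2107 none, with 68 further control probe sets. Symbols were checked through gene identifiers against a human RefSeq gene table, in which 19053 probe sets matched and 0 symbols changed. Probe sets with several symbols were not named. The 11963 genes with a single symbol were represented by the probe set with the highest mean log2 signal, and list levels and SDs used log2 values averaged over a gene's probe sets. Named genes were chosen by a rule fixed at that same early stage, which takes DACH1, the members of 22 gene lists and the 10 probe sets with the largest SD among those above the median level. Within lists, the examples are mostly the members with the largest SD, and a further list of 25 variable genes above background was added after the values were seen. The lists cover TGF-beta induced genes, TGF-beta ligands, receptors and SMADs, the retinal determination network with SKI and corepressors, AP-1, cell cycle, DNA replication, extracellular matrix, proteases, chemokines, interferon response, epithelial and mesenchymal genes, heat shock, apoptosis, cholesterol synthesis, glycolysis, ribosomal proteins, nuclear receptors and markers of luminal, fibroblast, leukocyte, and endothelial and erythroid cells.

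In a test added after the data were seen, the SD of each list was set against 10000 random lists of the same size, matched on level in 20 bins, with 2-sided p-values adjusted by Benjamini-Hochberg over the 22 lists. This test treats genes as independent, and genes that vary together make its p-values too small. The steps were tested on simulated data of 22283 probe sets with noise of SD 0.22. Of 100 probe sets given an added SD of 0.5, 85% were among the 200 with the largest SD, and 100% were with an added SD of 1. A planted list, in which every member had an added SD, reached the percentile 100, and 0 of 20 lists without an effect passed an adjusted p of 0.05. The simulated noise was independent between probe sets, so this does not check the rate of false calls where genes vary together. Alternatives were the deposited values without scaling, scaling to the same MAD, quantile normalization, log2 of the signal plus 1, leaving out the dimmest 25% of probe sets, single probe sets in place of gene averages, Spearman correlation, the interquartile range and each array left out in turn. Another background bound, a limit of 3 times, arrays 6 and 8 left out together, and scaling, quantile normalization or genes above background for the list percentiles were added after the data were seen. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.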

Results

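MDA-MB-231 cells, an established line of triple-negative human breast cancer cells, were profiled on 9 single-channel oligonucleotide arrays of 22283 probe sets each. The labels described cells carrying an inducible DACH1 construct together with a plasmid for the receptor that drives it, selected with Zeocin and G418. DACH1 is a nuclear protein of the retinal determination network that acts with corepressors, and the series title placed it as an inhibitor of TGF-beta signalling that binds SMAD4. Induced DACH1 protein on a western blot was mentioned for 8 of the 9 arrays. The labels put the arrays in a single group and gave no state of induction or ligand treatment for any of them, so no groups were compared. Arrays are named 1 to 9 by the number in their titles. Values are signals after scaling to a common median, listed in the order of arrays 1 to 9 where 9 values stand together, and each SD is over the 9 arrays on the log2 scale (n = 9). These SDs and ranges contain any difference in treatment between the arrays that the labels leave out, so they cannot serve as replicate error.

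The arrays had similar value distributions. Deposited median signals ran from 146.8 to 163.2, and the SD of log2 signals within an array averaged 2.64 and ran from 2.54 to 2.70, with the narrowest values on arrays 6 and 8. Between 61.5% and 73.8% of probe sets on an array exceeded its highest bacterial control, the bound used for background. Over the 36 pairs of arrays, Pearson correlations across probe sets ran from 0.953 to 0.972 with a median of 0.964. Signal ratios between the 5' and 3' probe sets, a sign of RNA integrity, were 1.10 to 1.20 for GAPDH and 0.879 to 0.922 for actin. Ribosomal RNA signals differed more, with the 28S 3' probe set from 282 on array 7 to 608 on array 6 and the 18S 3' probe set from 123 on array 2 to 288 on array 9. Array 1 carried a mouse organism label and array 2 named another receptor plasmid than the rest, and their median correlations with the other arrays were 0.967 and 0.964.

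DACH1 had the widest range of the 7519 genes above background on all arrays. Its brighter probe set measured 182, 234, 238, 5704, 5128, 5442, 2459, 2233 and 2879.7 on arrays 1 to 9. The highest signal, on array 4, was 31.4 times the lowest, on array 1, and the SD was 2.10. All 9 values exceeded the background bound of their array. The other DACH1 probe set gave signals from 6.20 on array 2 to 40.8 on array 7 and lay under the bound on all 9 arrays, so it measured no DACH1 range.

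**Figure D1:**
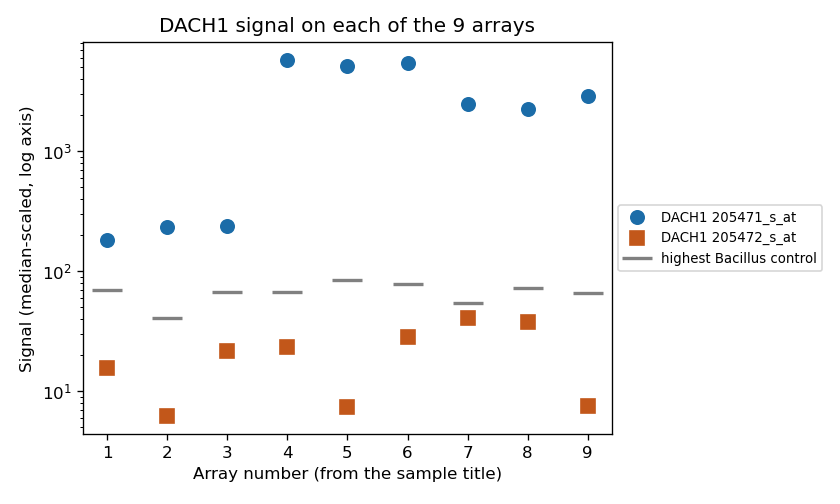
Signal of the DACH1 probe sets on each of the 9 arrays, with the array number on the horizontal axis and the median-scaled signal on a log axis. Circles are the brighter probe set, which ran from 182 to 5704, squares are the other, which stayed at or under 40.8, and grey bars are the highest bacterial control of each array.

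Among the 7519 genes above background on all 9 arrays, 1375 (18.3%) had a highest signal at least 2 times their lowest, and 34 reached 4 times. The median SD of these 7519 genes was 0.22. Arrays 6 and 8 weighed on that count, which was 813 of 7676 genes (10.6%) when both were left out, a setting chosen after the values were seen. Leaving out any 2 arrays lowered the count, which over all 36 pairs ran from 813 to 1277 with a median of 1105. Among probe sets above the median level, with no filter on background, those with the largest SD after DACH1 were for DUSP1, SPDEF, CCNE2, ITGB5, POP1 and PAGR1 together with 3 unnamed probe sets. DUSP1, a phosphatase that switches off MAP kinases, measured 222, 207, 221, 1617, 1465, 1572, 413, 465 and 654 with its dimmer probe set (SD 1.24). Its brighter probe set spanned a ratio of 3.06. CCNE2, which encodes cyclin E2 and drives entry into S phase, measured 795, 782, 724, 91.6, 191, 131, 790.1, 555 and 551 (SD 1.23), and its other probe set spanned 5.11 times. ITGB5, an integrin subunit, had 186, 282, 244, 1461, 1554, 244, 269.6, 170.3 and 346 with 1 of its probe sets (SD 1.20). Its brightest probe set spanned 1.38 times and so did not show this wide range. These SPDEF, POP1 and PAGR1 probe sets lay under the background bound on at least 1 array. Another SPDEF probe set lay above it on all 9 and ran from 79.3 on array 4 to 352 on array 7 (4.44 times). For POP1, arrays 6 and 8 gave 37.9 and 41.1 and the other arrays 178 to 277. For PAGR1, array 6 gave 42.2 and the other arrays 174 to 475.

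A wider list, the 25 named genes above background with the largest SD, was formed after the values were seen and uses the probe set with the largest SD of each gene. In it LAPTM5, a lysosomal membrane protein, measured 570.04, 634, 559.9, 2029, 1640.4, 1495, 2602, 2288 and 2929.7 (SD 0.97). MMP9, a gelatinase, measured 214, 218, 194, 337, 283, 347, 820.3, 845 and 809.6 (SD 0.88). AKAP12, a scaffold for protein kinases, ran from 824 on array 3 to 3242 on array 4, and KLF6, a zinc finger transcription factor, from 486 on array 3 to 1787 on array 5. RGS20, a regulator of G protein signalling, was lowest at 128 on array 6 and highest at 798 on array 3. EIF5, a translation initiation factor, had 2444, 2649, 2589, 705, 979, 438, 2154, 1675 and 2008, and H4C8, a replication-dependent histone gene, had 349, 573, 726, 107, 97.0, 131, 225, 331 and 168. SLC16A7, a monocarboxylate transporter, measured 111 on array 8 and 454 to 634 on the others.

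**Figure D2:**
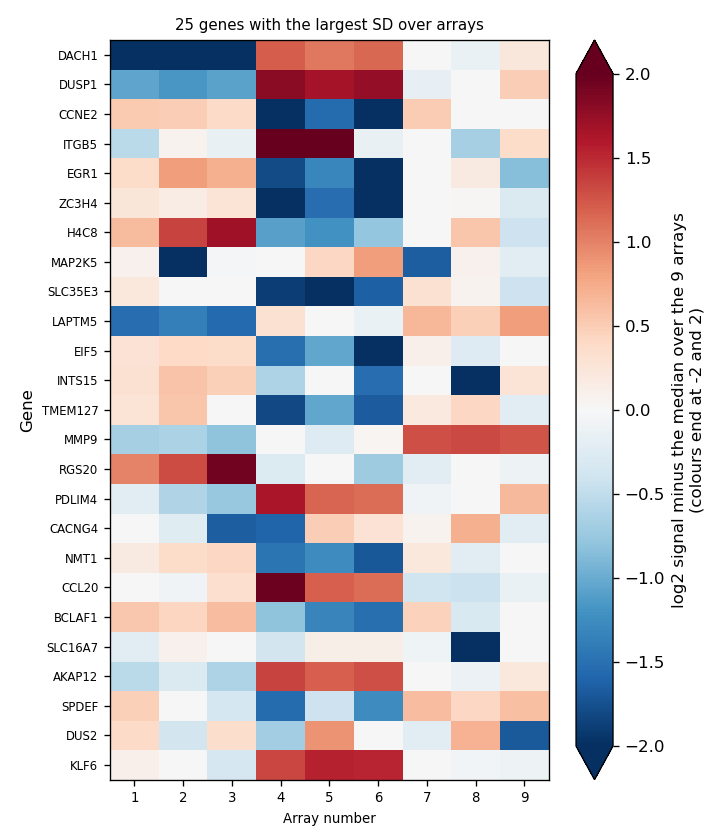
Heat map of the 25 named genes above background with the largest SD, with genes as rows and arrays 1 to 9 as columns. Colour is the log2 signal minus the gene's median over the 9 arrays and ends at -2 and 2, and DACH1, at the top, had an SD of 2.10.

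The title's subject, TGF-beta signalling, was covered by a list of target genes and a list of pathway components. Of the TGF-beta induced genes, 7 of the 15 above background had a range of at least 2 times, and 6 of 16 did without arrays 6 and 8. CCN1, a matricellular protein, measured 6126, 7161, 5434, 15517, 15686, 18076, 5676, 6025 and 7683 (SD 0.71). This probe set spanned 3.33 times and the other CCN1 probe set 2.01 times. CCN2, a relative of CCN1 also known as connective tissue growth factor, measured 2509, 2594, 2725, 4896, 4420.1, 5501, 2065, 1959 and 2533 (SD 0.55). ID1, an inhibitor of basic helix-loop-helix factors, measured 2864, 2561, 2089, 6309, 5681, 7657, 5542, 6075 and 4985 (SD 0.67). The cell cycle inhibitor CDKN1A ran from 949 on array 3 to 1946 on array 7, the inhibitory SMAD7 from 112 on array 5 to 269 on array 8 and the secreted adhesion protein TGFBI from 300.2 on array 3 to 738 on array 7, and IGFBP3 also passed 2 times. CCN1, ID1, TGFBI and CDKN1A were lowest on array 3, and CCN1, CCN2 and ID1 were highest on array 6. These arrays did not stand alone. CCN1 and CCN2 were higher on each of arrays 4, 5 and 6 than on any other array. ID1 was lower on each of arrays 1, 2 and 3 than on any other. No test of a shared order of arrays was run. Among ligands, receptors and SMADs, 6 of the 23 genes above background passed 2 times, among them BMP7 (ratio 2.85), ACVR2B (2.40) and SMAD1 (2.46). Without arrays 6 and 8, 5 of 23 did. BMP4, another ligand, had a larger SD (1.46) but lay under background on at least 1 array, with signals from 29.3 on array 6 to 349 on array 1. SMAD4, the common partner of the receptor-activated SMADs, measured 791, 668, 710.2, 541, 509, 422, 751, 561 and 639 and spanned 1.88 times. The receptor gene TGFBR2 spanned 1.62 times around a median of 1973, and SMAD2 1.35 times around 1113.

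Of the retinal determination network and its corepressors, a list that leaves out DACH1 itself, 2 of the 7 genes above background passed 2 times, and the count was 1 without arrays 6 and 8. CREBBP, an acetyltransferase coactivator, measured 629, 587, 567, 269, 304, 309, 534, 568 and 470.1 (SD 0.48), whereas the deacetylase genes HDAC1 and HDAC3 spanned 1.30 and 1.43 times. Of the AP-1 and immediate early genes, 4 of the 13 above background passed 2 times, namely EGR1, DUSP1, ATF3 and IER2. EGR1, a zinc finger factor induced by growth signals, measured 983, 1362, 1245, 220.2, 307, 186, 762, 865 and 421 (SD 1.09) with its brighter probe set and spanned 2.75 times with the other. IER2 ran from 2775 on array 6 to 7018 on array 3. JUN, a core AP-1 subunit, ran from 2509.5 on array 3 to 4941 on array 6, and MYC from 3335 on array 8 to 6306 on array 5. This JUN probe set spanned 1.97 times, and its other probe sets above background 1.94 to 2.84 times.

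DNA replication genes were among the groups with the most wide-ranging members. All 22 measured members were above background and 10 of the 22 spanned at least 2 times, which became 7 of 22 without arrays 6 and 8. PCNA, the sliding clamp of the replicative polymerases, measured 3622, 3593, 3233, 1825, 2672, 1163, 3125, 1988 and 3566 (SD 0.57). CDC6, which loads the replicative helicase, had 1537, 1786, 1366, 659, 813, 556, 1331, 1329 and 1159.7 (SD 0.58), and the flap endonuclease gene FEN1 had 3363, 3405, 2627, 1369, 1805, 1048, 2919, 1961 and 2523 (SD 0.59). The helicase subunits MCM2 to MCM6 all passed 2 times, with MCM2 at 3881, 3603, 2876, 1748, 1773, 1694, 3219, 2505 and 2739. Array 6 gave the lowest and array 4 the next lowest signal for each of CDC6, FEN1, PCNA and MCM2. Among cell cycle and mitosis genes, 6 of the 27 above background passed 2 times, against 3 of 28 without arrays 6 and 8. They included CCND2, encoding a G1 cyclin, with 162, 141, 117, 315, 273, 313, 161, 177 and 162, and the spindle motor genes CENPE (2.28 times) and KIF11 (2.12 times).

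**Figure D3:**
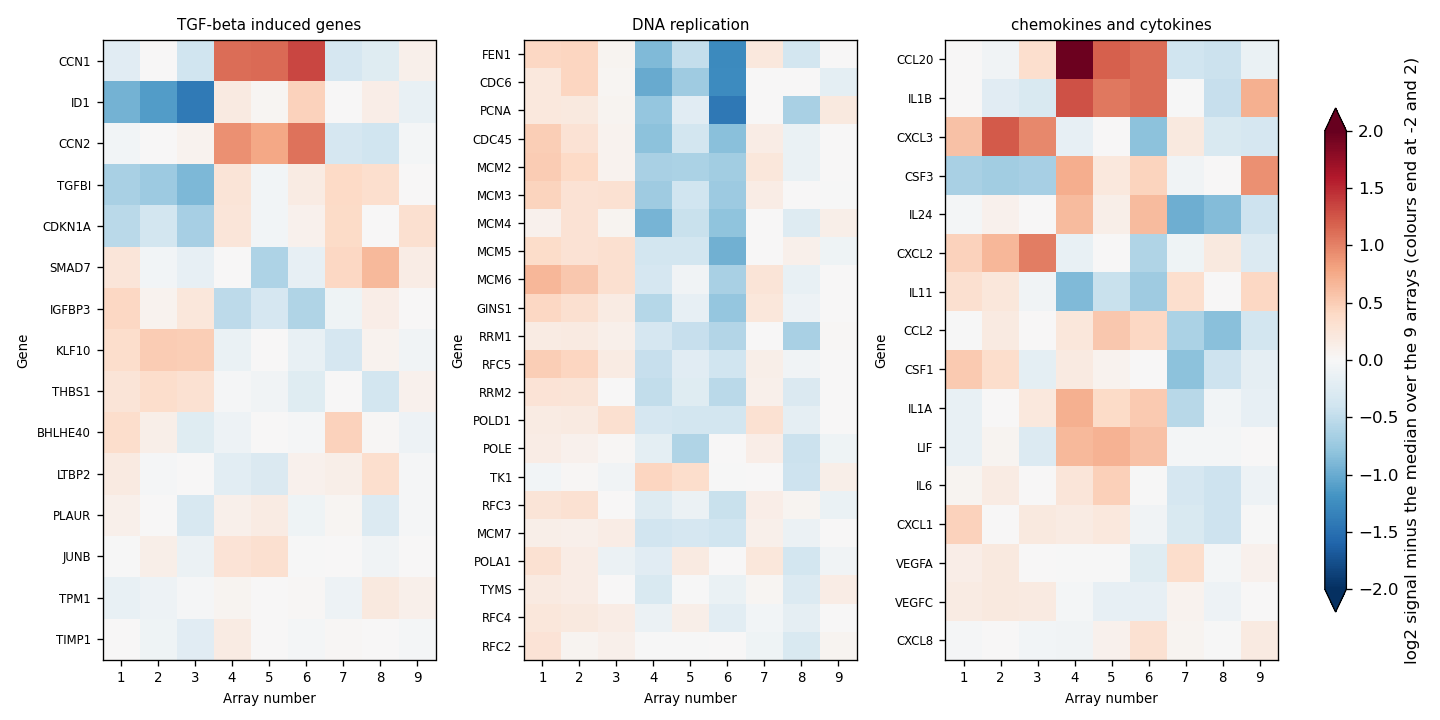
Heat maps of the genes above background in 3 lists, namely TGF-beta induced genes, DNA replication genes, and chemokines and cytokines, each sorted by SD with arrays 1 to 9 as columns. Colour is the log2 signal minus the gene's median over the 9 arrays and ends at -2 and 2, and 7 of the 15, 10 of the 22 and 10 of the 16 genes shown passed a range of 2 times.

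Of the chemokine and cytokine genes, 10 of the 16 above background spanned at least 2 times. CCL20, a chemoattractant for lymphocytes and dendritic cells, measured 512, 486, 648, 2003, 1179, 1109.95, 387, 379 and 469 (SD 0.84). The inflammatory cytokine gene IL1B measured 1441, 1232, 1168, 3475, 2990.2, 3142, 1429, 1046 and 2355 (SD 0.68), and CXCL3, which attracts neutrophils, had 827, 1292, 1071, 494, 552, 315, 633, 447 and 436 (SD 0.66). CSF3 ran from 267 on array 2 to 818 on array 9 and CXCL2 from 1977 on array 6 to 6136 on array 3, whereas CXCL8 spanned 1.30 times around a median of 11892. Among proteases and their inhibitors, 4 of the 17 passed 2 times, led by MMP9 and followed by MMP3, PLAT and CTSK. PLAT, tissue plasminogen activator, ran from 2352 on array 3 to 5279 on array 4. The collagenase gene MMP1 was brighter, with a median of 7660.4, and spanned 1.77 times. Of extracellular matrix and integrin genes, 5 of the 21 passed 2 times. The integrin subunit genes ITGA2 and ITGA3 ran from 533 on array 9 to 1697 on array 1 and from 1143 on array 3 to 2959 on array 7, and the collagen genes COL4A1 and COL5A1 from 473 on array 3 to 1268 on array 4 and from 157 on array 3 to 381 on array 7.

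CDH1, which encodes E-cadherin, stayed at or under 45.4 with its brighter probe set, under background on all arrays, while VIM, which encodes vimentin, had a median of 17594 and spanned 1.37 times. Of the epithelial genes, 3 of the 13 above background passed 2 times, namely CLDN7, CLDN4 and KRT18, and 2 of 13 did without arrays 6 and 8. CLDN7, a tight junction protein, measured 447, 357, 231, 607, 602, 606, 430.2, 274 and 424. Of the mesenchymal genes, 1 of the 7 did, which was ACTA2, smooth muscle actin, with 248, 238, 191, 454, 392, 469, 236, 235 and 253. Of the interferon response genes, 2 of the 22 above background passed 2 times (IFITM1 and IFI6), and 1 of 22 without arrays 6 and 8.

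Among heat shock and unfolded protein response genes, 6 of the 19 passed 2 times, and 5 of 19 did without arrays 6 and 8. HSPA5, the main chaperone of the endoplasmic reticulum, measured 6675, 6985, 5589, 14071, 14364, 14072, 9190.1, 8340.5 and 9897 (SD 0.51). TRIB3 and ASNS, both targets of the amino acid response, ran from 388 on array 6 to 1507 on array 2 and from 939.8 on array 6 to 3217 on array 2. Apoptosis genes gave 3 of the 17, with the survival factor MCL1 from 4639 on array 3 to 14429.5 on array 6 and the caspase inhibitor CFLAR from 816 on array 8 to 2178 on array 6. Other probe sets of these 2 genes spanned as little as 1.91 and 1.31 times. Of the cholesterol and fatty acid synthesis genes, 3 of the 17 passed 2 times, led by SREBF1, a regulator of lipid synthesis, from 205 on array 4 to 581 on array 1. Glycolysis and hypoxia genes gave 2 of the 21, namely NDRG1 and HK2, and 1 of 21 without arrays 6 and 8. Nuclear receptors and their partners gave 4 of the 17, or 2 of 17 without these arrays, with PPARG, a regulator of lipid storage, at 222, 252, 234, 492, 489, 575, 235, 208 and 272. Of the ribosomal protein genes, 0 of the 19 passed 2 times, and their median SD was 0.11. It was 0.21 with each array scaled to the same MAD. The widest of them, RPL6, spanned 1.51 times.

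Among markers of other cells, each gene was read by its brightest probe set for the median signal of a list. This median was 231 for luminal breast, 74.4 for fibroblast, 63.0 for leukocyte, and 20.1 for endothelial and erythroid markers. The median level of 153 over all probe sets is not a like measure, since it includes the dimmer probe sets of genes. On the log2 scale, the luminal level was 7.00 with gene averages and 6.17 with single probe sets. Of the luminal breast markers, 3 of the 8 above background passed 2 times (ERBB3, FOXA1 and ESR1), or 1 of 8 without arrays 6 and 8, and ERBB3, a receptor of the EGF receptor family, ran from 212 on array 3 to 523 on array 6. Of the fibroblast markers, 4 of 10 were above background and THY1 alone passed 2 times. This rested on array 2, where THY1 measured 54.7 against 112 to 146 on the others. That value lay near the background bound of array 2, which at 40.5 was the lowest of all arrays. Of the leukocyte markers, 3 of 10 were above background and ITGAM alone passed 2 times, and 0 of 3 did without arrays 6 and 8. Of the endothelial and erythroid markers, 3 of 7 were above background, and KDR, a VEGF receptor, measured 104, 89.5, 76.6, 259.7, 188, 240.3, 179, 165 and 177. The leukocyte marker CD3E (median 126) and the erythroid marker HBB (median 170) also passed the bound on all arrays. Passing it therefore does not show that a marker such as ESR1 or FOXA1 is expressed in this line. Probe sets for the same gene did not always give the same result, since 29 of the 136 list genes with a second probe set above background had probe sets on both sides of a range of 2 times.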

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

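The tests on DACH1 and on the mouse label were chosen after those results were seen, and the test on arrays 6 and 8 was written before its result was seen. In 3 of 148 results, a single array lay far from the other 8. Chance alone gives about 1 in 20 for results that were not selected, on arrays that do not differ. Many of these results, PAGR1 and THY1 among them, were picked for their spread, so no count expected by chance is given. PAGR1 had a log2 signal of 5.45 on array 6, and the nearest other array was at 7.46. THY1 had 5.81 on array 2, and the nearest other array was at 6.83. Its signal on array 2, 54.7, was near the background bound there, which at 40.5 was the lowest of all arrays. SLC16A7, also picked for its spread, after the values were seen, had 6.81 on array 8 against 8.83 on the nearest other array.

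DACH1 spanned 31.4 times between arrays, the widest range of the named genes. Array brightness or scaling would move the spiked hybridization controls as well, but the widest of these 18 control probe sets spanned 1.69 times, and the DACH1 ratio was 33.3 as deposited, 37.6 after MAD scaling and 31.5 after quantile normalization. A transcript that the dimmer probe set does not read, such as one from a construct, may account for the range being seen by the brighter probe set alone. The dimmer one reached at most 40.8, under the background bound everywhere, which a weak probe set would also give, so these cannot be told apart without the probe positions. The labels give no state of induction per array, so no biological explanation was tested.

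The mouse label on array 1 might mean that mouse RNA was hybridized. Its median correlation with the other arrays was 0.967, within the 0.958 to 0.967 of the 9 arrays, which argues against this. A slip in the organism field stays open and was not tested. No biological explanation was tested.

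Arrays 6 and 8 had the narrowest range of values. As deposited, their median log2 deviations from the median array were 0.21 and 0.19 in the lowest of 4 bins of level and 0 in both upper bins. The deposited arrays share a trimmed mean, on which bright probe sets weigh most, so this does not place the difference at the low end. A deviation of 0 also says little, since each array's own values enter the median array. Arrays 4, 5 and 9 gave 0 in all 4 bins. Median scaling made the deviations of arrays 6 and 8 0.12 and 0.11 in the lowest bin and -0.10 and -0.09 in the top bin. A constant background added to every probe set could compress the low end and would add about the same signal in both lower bins. The deposited excess in the second bin was instead at least 4.72 times that in the lowest on both arrays. This argues against a constant left in the deposited values as the whole cause. A constant in the raw scans was not tested, since the background correction was not given. A difference in hybridization or labelling stays open, since the labels give no batch. No biological explanation was tested.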

How the results depend on the processing

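The settings with a limit of 3 times, another background bound, arrays 6 and 8 left out together, and those for list percentiles were chosen after the data were seen, and the rest had been planned. Without single arrays, the DACH1 ratio was 24.3 to 31.4 and its SD 1.90 to 2.23. As deposited, after MAD scaling and after quantile normalization, the ratio was 31.5 to 37.6. In these 3 settings the DACH1 SD moved by less than its jackknife standard error, which was made from the values without single arrays. The ratio had been held against the DACH1 SD of 2.10 on the log2 scale, a limit too wide to test it. SDs of other probe sets, all named in the text or picked for their spread, moved by more than their own spread for 13 without arrays 6 and 8, 7 after MAD scaling, 3 after quantile normalization and 1 as deposited. Without single arrays 6 moved: THY1 from 0.41 to 0.12 without array 2, PAGR1 from 1.09 to 0.47 and PCNA from 0.57 to 0.39 without array 6, and SLC16A7 from 0.80 to 0.17, RARG from 0.42 to 0.27 and FOXA1 from 0.31 to 0.18 without array 8. POP1 went from 1.14 to 0.21 without arrays 6 and 8. The rest of the SDs stayed within their spread. For SDs of probe sets and lists, this spread is a jackknife standard error made from the values without single arrays. Those same values could hardly exceed it, so staying within it says little about leaving out single arrays. The median correlation of 0.964 became 0.971 with Spearman and 0.720 over the most variable 25% of probe sets, and was 0.963 to 0.965 without single arrays. The spread within arrays of 2.64 became 1.99 without the dimmest 25% and 3.86 as an interquartile range, which is another measure, and was 2.64 to 2.66 without single arrays. The count of 1375 genes was 1273 to 1614 under other scalings and bounds, 150 at 3 times, 1089 to 1339 without single arrays and 813 without arrays 6 and 8, the lowest of the 36 pairs left out (median 1105). Fewer arrays narrow a range by construction.

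Percentiles of list spread for DNA replication (100 in each) and chemokines (99.98 to 100) kept adjusted p-values under 0.05 without any single array. Leaving out a single array does not remove a difference that several arrays share. The check therefore says little about whether such a difference lies behind these calls. TGF-beta induced genes ran from 99.29 to 99.98 and missed 0.05 in the permutation test without array 3 (99.47, adjusted p = 0.0792) and without array 5 (99.29, adjusted p = 0.0792). Ribosomal genes ran from 0.08 to 1.95 and missed it without array 1 (0.78), 3 (1.95), 4 (0.96), 8 (1.30) or 9 (0.57), without arrays 6 and 8 (2.33), with genes above background (0.89) and as deposited (2.77), and lay at 80.62, on the other side of the random median, after MAD scaling. AP-1 ran from 97.7 to 99.73 and passed it without array 6 (99.73), without arrays 6 and 8 (99.60) and with genes above background (99.62), as did heat shock without arrays 6 and 8 (99.54). The cause was not tested.

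Median SDs of lists past their spread were 0.36 for the DACH network, 0.25 for interferon, 0.33 for epithelial, 0.24 for cholesterol, 0.22 for glycolysis and 0.21 for ribosomal after MAD scaling; 0.33 for the DACH network, 0.17 for glycolysis and 0.0901 for ribosomal after quantile normalization; 0.30 for TGF-beta induced, 0.26 for the DACH network, 0.35 for fibroblast and 0.31 for endothelial and erythroid without the dimmest 25%; 0.30 for TGF-beta components, 0.37 for the DACH network, 0.35 for matrix, 0.24 for apoptosis, 0.21 for cholesterol, 0.13 for ribosomal, 0.32 for nuclear receptors and 0.50 for luminal with single probe sets; and 0.22 for TGF-beta components, 0.18 for cell cycle and 0.44 for leukocyte without arrays 6 and 8. Without single arrays, apoptosis ran from 0.17 to 0.18 and TGF-beta components from 0.24 to 0.25. Median log2 levels past their spread were 9.31 for TGF-beta induced, 7.84 for TGF-beta components, 7.37 for the DACH network, 10.09 for AP-1, 8.63 for matrix, 8.79 for epithelial, 9.20 for mesenchymal, 9.30 for cholesterol, 7.49 for nuclear receptors, 7.36 for luminal, 6.32 for fibroblast, 6.42 for leukocyte and 7.21 for endothelial and erythroid without the dimmest 25%, which removes low members, and 7.51 for TGF-beta components, 6.38 for the DACH network, 9.48 for AP-1, 6.74 for matrix, 9.56 for chemokines, 9.29 for interferon, 7.86 for epithelial, 8.81 for mesenchymal, 8.37 for apoptosis, 10.11 for cholesterol, 11.76 for glycolysis and 6.17 for luminal with single probe sets. The cause of the others was not tested. Tests on log ratios, array weights, robust fits, sign flips and set tests were not run, since the values are no ratios, and filters on missing values had none to remove. Signals near the bacterial controls are limited by background. No paired analysis was possible because the labels give 1 group.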

Other observations

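The comparison of lists with random lists was added after the data were seen but before its own result was known, and the steps in DACH1 and the correlations of deviations were chosen after the values were seen. Against 10000 random lists matched on level, the median SD of the DNA replication genes lay at percentile 100 (adjusted resampling-test p = 0.0044, 22 genes). Their median SD was 0.40 and that of the random lists 0.19. This resampling test drew genes at random and did not shuffle arrays. The chemokine and cytokine genes lay at 99.99 (adjusted resampling-test p = 0.0044, 19 genes), with 0.37 against 0.21. TGF-beta induced genes lay at 99.8 (adjusted resampling-test p = 0.0231, 22 genes), with 0.37 against 0.24. The ribosomal protein genes lay at 0.17 (adjusted resampling-test p = 0.0231, 19 genes), with 0.11 against 0.16. However, they lay at 80.62 with each array scaled to the same MAD (adjusted resampling-test p = 0.533) and at 2.77 as deposited (adjusted resampling-test p = 0.211). Whether they were steadier than other bright genes stays open. For the other 3 lists the values argue against a chance draw of genes of the same level, as far as a test that treats genes as independent goes. The TGF-beta call was lost without array 3 or array 5, and the ribosomal call without array 1, 3, 4, 8 or 9. AP-1 and immediate early genes lay at 98.75 (adjusted resampling-test p = 0.111, 16 genes), with 0.30 against 0.21. The other 17 lists had adjusted resampling-test p-values from 0.249 to 0.870. What stays open is which condition, batch or culture differed between the arrays, since the labels record none.

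Ranked by DACH1 signal, the arrays were 1 (182), 2 (234), 3 (238), 8 (2233), 7 (2459), 9 (2879.7), 5 (5128), 6 (5442) and 4 (5704). The largest steps were 9.37 times between arrays 3 and 8 and 1.78 times between arrays 9 and 5, and the other steps were at most 1.29 times. The DACH1 signals lay in separate ranges, and these were those of title numbers 1 to 3 (182 to 238), 7 to 9 (2233 to 2879.7) and 4 to 6 (5128 to 5704). Correlations of each array's deviation from the mean were taken across the probe sets above the median level only. They ran from -0.61 to 0.55 over the 36 pairs, and independent arrays would give about -0.125. Pairs among arrays 1 to 3 had 0.52, 0.35 and 0.39, pairs among arrays 4 to 6 had 0.55, 0.53 and 0.45, and pairs among arrays 7 to 9 had 0.14, 0.24 and 0.0089. Arrays 1 and 7 had 0.27 and arrays 2 and 7 had 0.19, above those of arrays 7 and 8 and of arrays 8 and 9. The 9 pairs of arrays 1 to 3 with arrays 4 to 6 ran from -0.61 to -0.37. The labels do not say what the numbers stand for, so no group was formed from them, and every SD and every range without single arrays contains whatever sets these arrays apart. For the same reason no correlation of other genes with DACH1 over arrays was computed.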
